A study of Mus musculus with 12 samples.

How the data were processed

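RNA of the quadriceps femoris was sequenced in 12 libraries from C57BL/6 mice of 18 weeks or 28 months that were sedentary or ran on a treadmill for 8 weeks, with 3 libraries in each of the 4 groups. Per the labels' protocols, the muscle was snap-frozen, RNA was extracted with Trizol, and the libraries were supplied ready-made. Per the submitters' processing notes, bcl2fastq 2.20.0.422, Trimmomatic 0.36, STAR 2.5.2b and featureCounts of Subread 1.5.2 were used with the mouse genome GRCm38, and DESeq2 is also listed there. The deposited values are integer counts per gene and library, per the file headers produced by featureCounts, with 49315 genes in each file, and no values of the authors' differential expression analysis entered the results here. Gene symbols were assigned to 48970 of the gene identifiers, and coordinates are those of the files. The annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here, so counts of paralogs, antisense genes and overlapping genes (immunoglobulin and haemoglobin genes, for example) are uncertain. The labels do not state sex.

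Libraries were grouped by the labels' age and treatment. All choices of comparisons, gene lists and alternatives were made before the data were examined, except those named below as added. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 15304 genes, and libraries were scaled by the trimmed mean of M values (TMM). A robust quasi-likelihood model with 1 coefficient per group was fitted to all 12 libraries (8 residual degrees of freedom, 12 in total at the median gene, common biological coefficient of variation 0.207). Tested were exercise against sedentary in young and in old mice, the difference between these responses (old minus young), and old against young in sedentary and in exercised mice. P-values were adjusted by the Benjamini-Hochberg method over the 15304 genes of a comparison, and 0.05 was the threshold. Group levels given as mean ± SD (n = 3) are TMM-normalised CPM, and sex-linked and tissue marker levels of single libraries are CPM of the library's plain total. Also of the plain total are the group means without SD of genes on lists added later, of central neurons, glia, peripheral myelin and fibroblasts. The same holds for the ratios and mean log2 levels of the brain and nerve lists. Errors of log2 fold changes are approximate SE. They were derived as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic, and are least reliable for genes with few counts. Total counts of 23.3 to 27.6 M per library mean that a gene at 1 CPM has 23 to 28 counts, and fitted folds of genes with few counts depend on edgeR's prior count.

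Gene lists fixed in advance (42, of which 41 had the minimum of 5 tested members) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry, each adjusted over the lists of a comparison. Members past the threshold over all genes, and past it when adjusted over the list alone, were counted. The rule for the genes named was Arnt, the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold with a mean of at least 1 CPM in the higher group and no overlap between the groups (for the difference between responses, past the threshold only), without predicted genes, pseudogenes and clone names. It added from each list the 3 members with the smallest adjusted p past the threshold, or, as values, the 2 members with the smallest p of a list past camera with fewer than 2 members past, and, where fewer than 10 genes passed, those that passed and the 10 next smallest p, as values. The text names only part of that set, and a gene outside it is said to be chosen after its values were seen. Outside it are also the markers Myh7, Krt5, Krt14, Adipoq, Alb, Ucp1, Xist and Ddx3y, given as levels of single libraries or groups and picked after their values were seen.

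The analysis was tested on simulated counts drawn with the real means and library sizes, in which 200 genes were changed by 1.5-, 2- or 4-fold. The share recovered was 16.4%, 52.2% and 80.3% for exercise in young mice (15036 genes), 11.9%, 59.7% and 77.3% for exercise in old mice (15071 genes), and 4.48%, 16.4% and 69.7% for the difference between the responses (15046 genes). It was 14.9%, 58.2% and 84.8% for age in sedentary mice (15065 genes) and 22.4%, 52.2% and 80.3% for age in exercised mice (15055 genes). False calls were 7.02%, 7.08%, 10.3%, 6.61% and 7.44% of the calls in the same order. A planted list of 40 genes at 1.5-fold was called in each comparison and 0 of 41 unchanged lists were. The simulated genes varied independently of each other. The simulation therefore does not show how often camera at the preset correlation calls unchanged lists whose members vary together.

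Alternatives set in advance were DESeq2 size factors, no filter on low counts, exclusion of mitochondrially encoded genes, the Wald test of DESeq2 1.42.0, limma voom with sample weights, fits of only the compared groups, a replicate block in the old libraries and each library left out in turn. Added after the data were seen were a sex term, the omission of young sedentary library 2 together with old exercised library 6, and a restriction to genes with a mean of at least 5 CPM. Similarity of responses was measured by correlation of log2 fold changes across genes, and group labels were permuted over all 10 splits of the libraries compared, or, for the difference between responses, over 100 of the 200 possible splits (the real one and others drawn at random). Ratios of group means over the lists of brain and nerve genes were taken with 0, 0.01, 0.1 or 0.5 CPM added to each mean, a range tried after the result with 0.1 CPM was seen.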

Results

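Gene expression was measured by RNA sequencing in the quadriceps femoris, the large extensor muscle of the thigh, of C57BL/6 mice, an inbred laboratory strain. The 12 libraries fell into 4 groups of 3. Young mice were 18 weeks old and old mice 28 months old. At each age 1 group stayed sedentary while the other ran on a treadmill for 8 weeks, 3 times a week for 40 minutes, at speeds raised from 8 to 12 m/min. Total counts per library were 23.3 to 25.8 M in young sedentary, 24.4 to 26 M in young exercised, 24.2 to 27.6 M in old sedentary and 25.1 to 25.5 M in old exercised muscle. Between 20815 and 22118 genes had at least 1 count in a library, and 15304 genes were tested. The labels list the libraries of a group as separate samples without stating how many animals they came from, so p-values measure the spread between these samples. No pair of libraries within a group agreed within sampling noise, with chi-square over degrees of freedom from 11.8 to 82.7. The first principal component held 28.6% of the variance and separated all old from all young libraries.

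Some libraries carried signals other than the labelled age and treatment. Xist, the RNA that coats the inactive X chromosome, lay between 124 and 214 CPM of the library's plain total in 5 libraries and at 1.49 or below in the other 7. The Y-linked Ddx3y lay at 77.5 to 112 CPM in those 7 and at 0.287 or below in the 5. By this pattern 2 young sedentary, 2 young exercised, 0 old sedentary and 1 old exercised library came from females, so sex and age were unevenly mixed. Young sedentary library 2 contained the skin keratins Krt5 (143 CPM) and Krt14 (84.7 CPM), which were at 0.43 CPM or below elsewhere. Old exercised library 6 held Igkc, an antibody light chain, at 304 CPM (18.4 or below elsewhere) and the fat-cell hormone Adipoq at 107 CPM, and young sedentary library 1 held Adipoq at 147 CPM. Young sedentary library 1 also held the albumin gene Alb at 129 CPM (28.7 or below elsewhere) and Ucp1, of the adipocyte list, at 4.55 CPM (0.119 or below elsewhere). Myh7, the myosin of slow fibres, ranged from 1.09 to 635 normalised CPM within young sedentary and from 0.893 to 407 within old sedentary muscle.

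The series concerns ARNT and the adaptability of aged muscle to exercise, so Arnt is given first. Arnt encodes the partner subunit that the hypoxia-inducible factors and the aryl hydrocarbon receptor need to bind DNA, and the gene lies on chromosome 3 from 95434388 to 95497240 (GRCm38, ENSMUSG00000015522). Its normalised level was 52.6 ± 2.94 CPM in young sedentary, 55.9 ± 6.72 in young exercised, 58.8 ± 4.24 in old sedentary and 61.5 ± 5.18 in old exercised muscle (mean ± SD, n = 3 each). None of the 5 comparisons of Arnt passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By edgeR the log2 fold change was 0.09 ± 0.10 (SE) with exercise in young mice (adjusted p = 0.745) and 0.06 ± 0.099 with exercise in old mice (adjusted p = 0.901). By edgeR it was 0.16 ± 0.10 for old against young sedentary mice (adjusted p = 0.321) and 0.14 ± 0.10 for old against young exercised mice (adjusted p = 0.441). By edgeR the difference between the exercise responses was −0.02 ± 0.141 (adjusted p = 0.953). In edgeR, 0 of the 12 measured members of the list of ARNT and hypoxia-inducible factor genes passed in any comparison, and the list did not pass camera, with adjusted p from 0.343 to 0.958. Adjusted over the list alone, 0 members passed in 4 comparisons and 1 passed in the difference between exercise responses, Hif1an, the asparagine hydroxylase that restrains these factors (log2 difference −0.49, adjusted p = 0.0282 over the list alone, named after its values were seen).

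**Figure D1:**
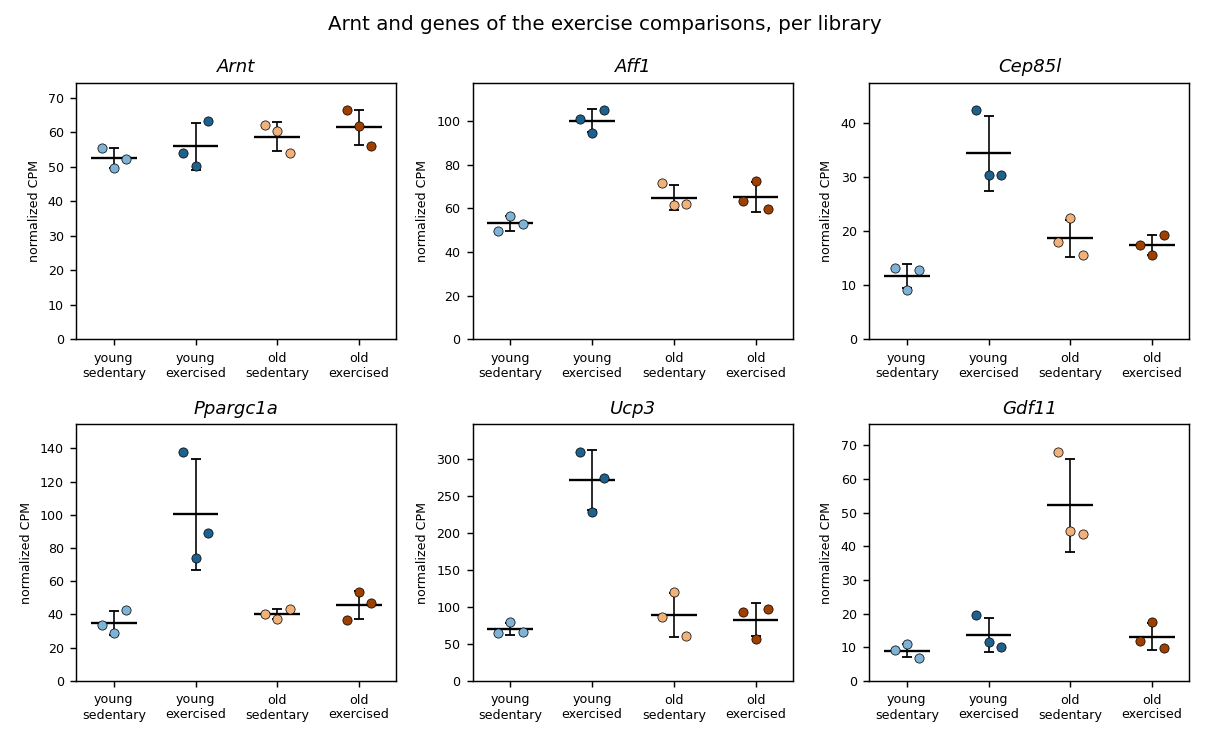
Normalised CPM (linear y axes from 0) of 6 genes in each of the 12 libraries by group (x axes), with points for libraries, bars for means and whiskers for 1 SD (n = 3). Arnt lay between 49.8 and 66.4 CPM in all libraries, Aff1 at 94.6 to 105 CPM in young exercised and at or below 72.8 in all others, and Gdf11 at 43.7 to 68.1 CPM in old sedentary and at or below 19.5 in all others.

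The first comparison asked what 8 weeks of treadmill running changed in young muscle. Aff1, which encodes a scaffold of the super elongation complex of transcription, rose from 53.1 ± 3.3 to 100 ± 5.42 CPM (n = 3 each; chromosome 5, 103692374 to 103855322), a log2 fold change of 0.92 ± 0.094 with an edgeR adjusted p of 0.00651. Cep85l, a centrosomal protein gene (chromosome 10, 53278081 to 53379851), rose from 11.7 ± 2.23 to 34.3 ± 6.92 CPM, a log2 fold change of 1.55 ± 0.185 (edgeR adjusted p = 0.0214). These 2 were the only genes past an adjusted p of 0.05, both higher in every exercised than in every sedentary library, while 1996 of the 15304 genes had an unadjusted p under 0.05 against 765 expected by chance. Ucp3, a mitochondrial carrier induced in muscle by fasting and exercise (chromosome 7, 100472990 to 100486432), stood at 70.2 ± 8.05 CPM in sedentary and 271 ± 40.2 CPM in exercised muscle. Its log2 fold change was 1.95 ± 0.262 and missed the threshold (edgeR adjusted p = 0.0631). Ppargc1a, the coactivator that drives mitochondrial biogenesis (chromosome 5, 51454250 to 51567726), stood at 35 ± 7.17 and 101 ± 33.6 CPM, a log2 fold change of 1.52 ± 0.231 with the same adjusted p.

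Other genes with the smallest p-values had the same edgeR adjusted p of 0.0631. Their log2 fold changes were 1.16 ± 0.181 for Lyve1, a hyaluronan receptor of lymphatic endothelium and resident macrophages, 1.03 ± 0.151 for Dkk2, a secreted modulator of Wnt signalling, and 1.58 ± 0.24 for Fibin. They were 0.59 ± 0.09 for the secreted ribonuclease Rnase4 and 0.62 ± 0.10 for the receptor Gpr146. Lower values were found for Srebf2, the transcription factor of cholesterol synthesis (−0.72 ± 0.116), and for Barx2, a homeobox factor of myogenic cells (−2.17 ± 0.34). Sorbs3, an adaptor of cell adhesion, had a log2 fold change of 0.79 ± 0.132 and Klf4, an immediate-early transcription factor, one of −0.78 ± 0.13 (both with an edgeR adjusted p of 0.075).

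Of the 41 fixed gene lists tested by camera with a preset correlation, 10 rose and 11 fell with exercise in young mice, each judged against the other genes. With an estimated correlation 0 of the 41 passed (smallest adjusted p 0.525), and fry called 0. No member of these lists passed over all genes tested, so the counts that follow are those adjusted over the list alone. The atrophy and autophagy list rose (camera adjusted p = 5.87e-08, and adjusted p = 0.525 with an estimated correlation), with 4 of 24 members higher adjusted over the list alone and a median log2 fold change of 0.20. Of its members, the muscle ubiquitin ligase Trim63 stood at 250 ± 30.1 and 635 ± 102 CPM. Fast-fibre genes rose (camera adjusted p = 1.08e-07, and adjusted p = 0.525 with an estimated correlation), with 11 of 17 higher adjusted over the list alone. Among them Actn3, the actinin of fast Z-discs, stood at 8960 ± 187 and 12600 ± 1050 CPM and Mybpc2 at 5410 ± 487 and 7560 ± 606 CPM. Calcium handling genes rose (6.94e-06, and adjusted p = 0.525 with an estimated correlation), with 3 of 22 higher adjusted over the list alone. Slow-fibre genes fell (6.94e-06, and adjusted p = 0.554 with an estimated correlation), with a median of −2.42 and 0 of 15 passing when adjusted over the list alone. Atp2a2, the calcium pump of slow fibres, stood at 246 ± 194 and 51.8 ± 9.82 CPM and Tnni1 at 39.5 ± 41.5 and 1.68 ± 1.06, and Myh7 ranged from 1.09 to 635 CPM among the sedentary libraries. Adipocyte markers fell (1.01e-06, and adjusted p = 0.554 with an estimated correlation), with 2 of 19 lower and 1 higher adjusted over the list alone, beside the fat-cell signal of young sedentary library 1. The fatty acid enzyme genes Elovl6 and Dgat2 stood at 17.5 ± 14.3 and 67.6 ± 32.6 CPM in sedentary and at 2.05 ± 0.622 and 18.2 ± 1.63 CPM in exercised muscle. These 5 lists kept their call without any 1 of the 6 young libraries.

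The other 16 lists that passed camera each lost their call when 1 library was left out. Without young sedentary library 2, the one with skin keratins, the adjusted p of camera became 0.293 for the falling cell cycle list, 0.382 for skin and hair markers, 0.102 for the falling Notch pathway, 0.0543 for tendon markers and 0.105 for glucocorticoid-responsive genes. The last 2 had risen, with Fmod, a tendon proteoglycan, at 93.8 ± 51.7 and 194 ± 20.8 CPM and Fkbp5, a glucocorticoid-induced chaperone, at 50.5 ± 26.5 and 168 ± 47.2 CPM. Fibro-adipogenic markers, which had risen, lost the call without that library (0.131) and without young exercised library 8 (0.0857). Without young sedentary library 3 it became 0.139 for endothelial markers and 0.557 for immediate-early genes, both lower with exercise, and 0.0813 for glycolysis genes, which had risen by median (0.23) and mean (0.05). Emcn, an endothelial sialomucin, stood at 10.8 ± 2.41 and 6.06 ± 1 CPM. Nuclear genes of oxidative phosphorylation had fallen by a median of −0.08 (camera adjusted p = 0.027) and changed direction without young sedentary library 3 (0.298), and lost the call without young exercised library 8 (0.328) or 10 (0.318). Fatty acid oxidation genes had fallen by a median of −0.24 (0.0414) and lost the call without young sedentary library 1 (0.855) or 3 (0.472) or without young exercised library 8 (0.185) or 10 (0.213). The remaining lists were macrophage markers (up, 0.233 without young exercised library 8), antigen presentation (down, 0.0962 without young sedentary library 1) and interferon response (down, 0.226 without young exercised library 7 and 0.454 without young sedentary library 3). Ribosomal proteins (up) had 0.188 without young exercised library 8 and 0.26 without young sedentary library 3. Erythroid genes (up) had 0.237 and 0.283 without young sedentary library 1 or 3 and 0.558 without young exercised library 10, and 0.109 with a sex term. Adjusted over the list alone, 3 of 15 fibro-adipogenic, 2 of 14 glucocorticoid-responsive and 1 of 28 fatty acid oxidation genes (Ucp3) were higher. By the same adjustment 4 of 5 skin, 3 of 13 antigen presentation, 2 of 24 immediate-early, 1 of 22 Notch, 1 of 22 endothelial and 1 of 34 interferon response genes were lower, and 0 passed in the other 7 lists. These 16 lists had adjusted p from 0.554 to 0.887 with an estimated correlation.

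The count of 2 genes rested on single libraries. It became 0 in edgeR without young exercised library 10 (1432 genes at an unadjusted p under 0.05) or young sedentary library 1 (1628 genes). It was 7 without young exercised library 7, 3 without young exercised library 8 and 33 without young sedentary library 2. Without young sedentary library 3 it was again 2 with 1 of the 2 genes shared. DESeq2 called 242 genes and limma voom 59, each including both genes, and a sex term raised the edgeR count to 10.

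The second comparison asked the same of old muscle. In the named set the genes that rose most were expressed at low levels in sedentary muscle and included several known from neurons. Snap25, a core protein of synaptic vesicle fusion, rose from 0.465 ± 0.248 to 5.39 ± 1.55 CPM (n = 3 each), a log2 fold change of 3.53 ± 0.457 (edgeR adjusted p = 0.00805). The glutamate receptor subunit genes Grin2a (3.21 ± 0.457, edgeR adjusted p = 0.0105) and Grin2b (3.52 ± 0.626, 0.0334) rose as well. So did the calcium sensor gene Vsnl1 (3.09 ± 0.413, edgeR adjusted p = 0.00816) and the neurofilament gene Nefl (3.09 ± 0.476, 0.0145). Add2, which encodes an adducin of the membrane skeleton, rose by a log2 fold change of 4.17 ± 0.57 (edgeR adjusted p = 0.00885), the vesicle GTPase gene Rab3c by 3.63 ± 0.591 (0.021) and Sult4a1 by 3.68 ± 0.676 (0.0372). Their fitted folds rest on few counts, since the 3 old sedentary libraries together held 4 counts of Add2, 6 of Sult4a1, 9 of Rab3c, 9 of Grin2b, 10 of Grin2a and 10 of Nefl. In all, 76 genes rose and 13 fell at an edgeR adjusted p under 0.05, and 75 of the 76 had a mean below 5 CPM. Among genes with a mean of at least 5 CPM edgeR called 0. RNA from central nervous tissue, weighed below, could give the rises of the genes known from neurons as well as exercise could.

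Of the 13 genes that fell with exercise in old mice 4 had a mean below 5 CPM. Gdf11, a secreted ligand of the transforming growth factor β family (chromosome 10, 128882295 to 128891718), fell from 52.2 ± 13.8 to 13.1 ± 4.02 CPM, a log2 fold change of −1.997 ± 0.309 (edgeR adjusted p = 0.0234). It stood at 9.01 ± 2.04 and 13.8 ± 5.05 CPM in young sedentary and exercised muscle. Sms, the spermine synthase gene (X chromosome, 157443855 to 157492287), fell from 181 ± 14.9 to 112 ± 7.75 CPM (−0.70 ± 0.107, edgeR adjusted p = 0.014). Kcnab1, a potassium channel subunit gene, fell from 16.8 ± 1.24 to 5.88 ± 2.69 CPM (−1.52 ± 0.288, edgeR adjusted p = 0.0451). The protease inhibitor gene Serpinb1a fell from 9.27 ± 0.722 to 4.84 ± 0.48 (−0.94 ± 0.183, 0.0455) and Zfp385b from 5.78 ± 2.48 to 1.52 ± 0.629 (−1.92 ± 0.376, 0.0478). Smaller falls were found for Pole4, a subunit of the replicative polymerase ε (−0.55 ± 0.101, edgeR adjusted p = 0.0372), Ccdc90b (−0.49 ± 0.091, 0.0372) and the translesion polymerase gene Rev1 (−0.42 ± 0.08, 0.0409). With a sex term Kcnab1 (edgeR adjusted p = 0.0513), Pole4 (0.0618), Ccdc90b (0.0542) and Rev1 (0.0606) missed the threshold, with ranges over all alternatives of 0.000163 to 0.28, 0.000887 to 0.267, 0.00132 to 0.28 and 0.00168 to 0.28.

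By camera with a preset correlation 5 lists rose and 2 fell in old mice. With an estimated correlation 0 of 41 passed and each of these 7 lists had adjusted p = 0.961 with an estimated correlation, and fry called 0. Calcium handling genes fell (camera adjusted p = 0.000279), with a median of −0.19, 0 of 22 past over all genes and 1 lower adjusted over the list alone, and this call held without any 1 of the 6 old libraries. Jph2, which anchors the sarcoplasmic reticulum to the T-tubule, stood at 1140 ± 128 and 804 ± 70.4 CPM (edgeR adjusted p = 0.0777). Fast-fibre genes fell (0.012), with Pvalb, the calcium buffer of fast fibres, at 8170 ± 1200 and 6240 ± 717 CPM and the deaminase gene Ampd1 at 1020 ± 54.9 and 751 ± 143 CPM. The call was lost without old exercised library 5 (0.0864) or 6 (0.0951) or old sedentary library 4 (0.0697), and 0 of 17 members passed when adjusted over the list alone. Endothelial markers rose (0.00518) with 21 of 22 members positive and 0 past when adjusted over the list alone, and lost the call without old exercised library 4 (0.345) or old sedentary library 4 (0.118). Eng, an endothelial coreceptor, stood at 32.6 ± 4.89 and 41.6 ± 5.35 CPM. Adipocyte markers rose (0.012), but without old exercised library 6, whose Adipoq level was 107 CPM, the direction reversed (0.713), and the call was lost without old sedentary library 4 (0.0669) or 5 (0.093). Erythroid genes rose (0.012) and lost the call without old exercised library 4 (0.161) or old sedentary library 4 (0.104), with Alas2, the erythroid heme synthesis gene, at 9.5 ± 6.06 and 23.9 ± 10.7 CPM. Ribosomal proteins rose (0.03) by a median of 0.09 and lost the call without old exercised library 4 (0.533) or 6 (0.876) or old sedentary library 6 (0.18) and with a sex term (0.0959). Adjusted over the list alone, 0 adipocyte, erythroid and ribosomal genes passed. Slow-fibre genes did not pass, and their median (−0.09) and mean (−0.15) differed in sign from the camera direction, which was up (0.728).

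Schwann cell and nerve markers rose in old exercised muscle (camera adjusted p = 0.012, and adjusted p = 0.961 with an estimated correlation), with 1 of 13 members higher over all genes, Nefl, and 2 adjusted over the list alone. The call was lost without old exercised library 4 (0.161) or 5 (0.144) or old sedentary library 4 (0.169) or 5 (0.0513). Of 20 astrocyte and oligodendrocyte genes listed after the rises above were seen, 20 had a higher mean in old exercised than in old sedentary libraries, some of them at very few counts. Their median log2 ratio of group means was 1.88, or 0.83 with 0.1 CPM added to each mean and 0.45 with 0.5 CPM added. The mean was also higher for 14 of 15 genes of central neurons, with medians of 1.67, 1.22 and 1.02. The 8 genes of peripheral myelin had medians of −0.014, −0.004 and 0.

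**Figure D2:**
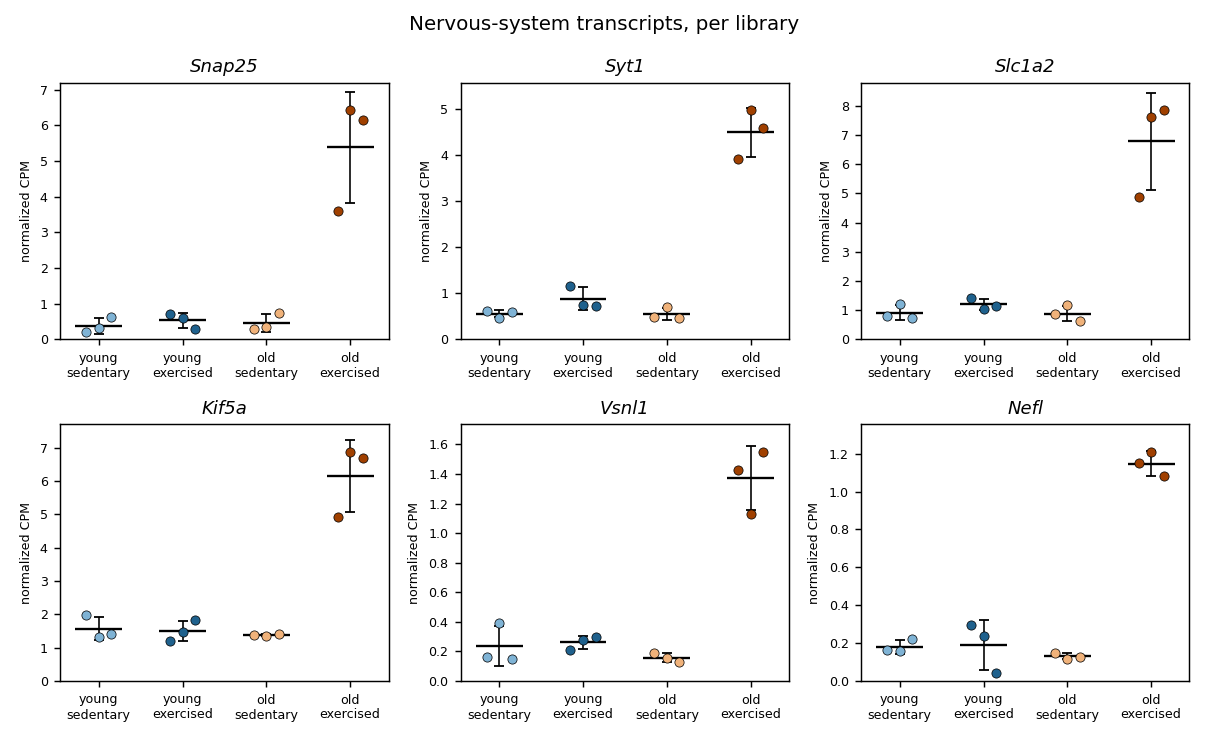
Normalised CPM (linear y axes from 0) of 6 nervous-system transcripts in each of the 12 libraries by group (x axes), with points for libraries, bars for means and whiskers for 1 SD (n = 3). Snap25 lay at 3.6 to 6.42 CPM in old exercised and at or below 0.75 in all other libraries, and Slc1a2 at 4.87 to 7.84 and at or below 1.42.

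Single libraries moved the count of 89 genes in old muscle to 29 without old exercised library 5, 21 without 6, 14 without old sedentary library 4, 10 without 5 and 13 without 6. Each of the 16 named genes that passed missed the threshold in at least 1 fit without a library. DESeq2 called 185 genes and limma voom 140, a fit of only the 2 groups called 57, and among genes with a mean of at least 5 CPM edgeR called 0 (666 at an unadjusted p under 0.05).

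The third comparison tested whether the exercise response differed between the ages. Aff1 rose with exercise in young mice (log2 0.92) and stood at 65.1 ± 5.59 and 65.3 ± 6.74 CPM in old sedentary and exercised mice. The difference of the responses, old minus young, was −0.91 ± 0.132 (edgeR adjusted p = 0.0417). Spock2, a proteoglycan gene of the extracellular matrix (chromosome 10, 60106219 to 60135198), stood at 7.29 ± 0.734 and 13.6 ± 1.76 CPM in young and at 24 ± 2.87 and 13 ± 3.48 CPM in old muscle. The difference was −1.79 ± 0.26 (edgeR adjusted p = 0.0417). The other 6 genes past the test had a more positive response in old mice. They were Kif5a, the neuronal kinesin (2.22 ± 0.324), Ddn, dendrin (2.85 ± 0.36), Tubb4a, a brain tubulin (2.66 ± 0.392), Enc1 (2.51 ± 0.35) and Jph3, the junctophilin of brain (6.595 ± 0.962), all with an edgeR adjusted p of 0.0417, and the adenylyl cyclase Adcy1 (2.37 ± 0.357, 0.0462). Jph3 had 12, 1, 5 and 60 counts in young sedentary, young exercised, old sedentary and old exercised libraries together, so its fitted value depends on the prior count. All 6 genes had a mean below 5 CPM, and among genes with a mean of at least 5 CPM edgeR called 0 for the difference. Several of the 6 are known from brain, so RNA from central nervous tissue, weighed below, could give their values as well.

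Further genes had an edgeR adjusted p of 0.0564. The differences were −1.65 ± 0.258 for Cep85l and −0.96 ± 0.15 for Sms, 2.37 ± 0.388 for the synaptic calcium sensor Syt1 and 2.56 ± 0.419 for the glial glutamate transporter Slc1a2. Ucp3 had a difference of −2.06 ± 0.362 (edgeR adjusted p = 0.075), with 89.4 ± 29.7 and 82.6 ± 22.5 CPM in old sedentary and exercised muscle. Klf4 had one of 1.04 ± 0.187 (0.0683).

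By camera with a preset correlation 13 lists differed in their exercise response, 9 more positive and 4 more negative in old mice, and with an estimated correlation 0 of 41 did (smallest adjusted p 0.47), and fry called 0. No list member passed over all genes. Calcium handling genes had a more negative response in old mice (camera adjusted p = 4.29e-08, and adjusted p = 0.47 with an estimated correlation), with a median difference of −0.39 and 10 of 22 lower adjusted over the list alone. Jph2 had a difference of −0.79 ± 0.154. Fast-fibre genes were more negative too (1.15e-07, and adjusted p = 0.47 with an estimated correlation), with 8 of 17 lower adjusted over the list alone, among the members with the smallest p Mybpc2 (−0.69 ± 0.166) and Ampd1 (−0.78 ± 0.198). Endothelial markers (4.27e-05, and adjusted p = 0.795 with an estimated correlation) and Notch pathway genes (0.00328, and adjusted p = 0.474 with an estimated correlation) were more positive. Adjusted over the list alone, 0 of 22 endothelial and 2 of 22 Notch genes passed. The Notch ligand gene Dll1 stood at 6.71 ± 1.67 and 3.47 ± 0.593 CPM in young and at 5.8 ± 1.05 and 7.48 ± 0.506 CPM in old mice. Adipocyte markers were more positive (1.91e-07, and adjusted p = 0.795 with an estimated correlation), with 5 of 19 higher adjusted over the list alone, beside Adipoq at 147 CPM in young sedentary library 1 and 107 CPM in old exercised library 6. Tendon markers were more negative (0.000719, and adjusted p = 0.795 with an estimated correlation), with 0 of 11 past adjusted over the list alone, and lost the call with young sedentary library 2 and old exercised library 6 left out together (0.152). The other 7 lists lost their call without 1 library or another. Slow-fibre genes (more positive, 0.000719) had 0.0682 without young sedentary library 3, and cell cycle genes (more positive, 0.00546) had 0.457 without young sedentary library 2. Nuclear oxidative phosphorylation genes (more positive, 0.00753) had 0.66 without young sedentary library 3, 0.0781 without old sedentary library 4 and 0.0704 and 0.0596 without young exercised library 8 or 10. Atrophy genes (more negative, 0.00759) had 0.0558 and 0.0691 without old exercised library 4 or 5. Fatty acid oxidation genes (more positive, 0.00939) had 0.182 and 0.0965 without young sedentary library 1 or 3, 0.0723 and 0.084 without old exercised library 5 or 6 and 0.106 without old sedentary library 4. Immediate-early genes (more positive, 0.021) had 0.287 without young sedentary library 3, 0.162 and 0.0599 without old exercised library 4 or 6, 0.0854 without old sedentary library 4 and 0.1 with a sex term. Skin markers (more positive, 0.0247) had 0.411 without young sedentary library 2, which held the keratins, and 0.0538 to 0.117 without old exercised library 4, 5 or 6, old sedentary library 4, 5 or 6 or young exercised library 7, 8 or 10. Adjusted over the list alone, 2 immediate-early genes were higher, 1 fatty acid oxidation gene was lower and 0 passed in the other 5 lists, and these 7 had adjusted p from 0.795 to 0.807 with an estimated correlation.

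The count of 8 genes became 0 in edgeR when any 1 of 11 libraries was left out, with 1698 to 2447 genes at an unadjusted p under 0.05. These were old exercised 4, 5 and 6, old sedentary 4, 5 and 6, young exercised 7, 8 and 10, and young sedentary 1 and 3. Without young sedentary library 2 the count was 57, including all 8. A sex term gave 0 genes in edgeR (2434 at an unadjusted p under 0.05), and DESeq2 called 430 and limma voom 71, each including the 8. Across the 15304 genes the log2 fold changes of exercise in young and old mice had a Pearson r of −0.223 and a Spearman rho of −0.222, and 40.7% of genes had the same sign, where genes are not independent replicates. The comparisons share no library, and r became −0.089 without old exercised library 6. No gene was called in both, but with 2 genes called in young mice only 0.00993 shared rises and 0 shared falls were expected from independent lists. The lack of shared calls therefore does not show that the responses differ.

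The fourth comparison set old against young sedentary muscle. Of 36 extracellular matrix genes 25 were lower in old muscle (camera adjusted p = 1.27e-39, and adjusted p = 0.154 with an estimated correlation). Sparc, a collagen-binding matrix protein gene (chromosome 11, 55394500 to 55423183), fell from 309 ± 49.2 to 95.7 ± 14.5 CPM (n = 3 each), a log2 fold change of −1.69 ± 0.164 (edgeR adjusted p = 0.000808). The basement membrane collagen gene Col4a2 fell from 124 ± 24.6 to 42.5 ± 10.3 CPM (−1.54 ± 0.177, 0.00133) and Serpinh1, the collagen chaperone of the endoplasmic reticulum, from 93.1 ± 21.1 to 26.8 ± 2.74 CPM (−1.80 ± 0.218, 0.0019). Camk2b, a calcium-dependent kinase gene (chromosome 11, 5969644 to 6066362), rose from 141 ± 11.3 to 285 ± 9.23 CPM (1.01 ± 0.072, edgeR adjusted p = 6.07e-05). Eda2r, a receptor induced by p53 (X chromosome, 97333840 to 97377216), rose from 12.1 ± 1.16 to 61.5 ± 15 CPM (2.34 ± 0.227, 0.000952). In all, 683 genes rose and 855 fell, 128 and 417 of them by at least 2-fold, and the median over all genes was −0.03.

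Of the 36 measured extracellular matrix genes 0 rose and 11 did not pass over all genes, 31 were lower adjusted over the list alone, and the median was −1.53. Fibro-adipogenic and fibroblast markers fell, 7 of 15 lower and 1 higher, and 8 lower and 1 higher adjusted over the list alone (9.17e-06, and adjusted p = 0.284 with an estimated correlation). They included the stromal genes Clec3b (−0.86 ± 0.111, edgeR adjusted p = 0.00194), Dpp4 (−1.51 ± 0.213, 0.00303) and Pi16 (−1.37 ± 0.248, 0.0101). Tendon markers fell, 4 of 11 lower, and 9 lower and 1 higher adjusted over the list alone (7.96e-05, and adjusted p = 0.571 with an estimated correlation). Cilp2 stood at 8.09 ± 3.96 and 1.28 ± 0.609 CPM and the cornea and tendon proteoglycan Kera at 12 ± 7.03 and 2.92 ± 1.14 CPM. Endothelial markers fell, 4 of 22 lower and 15 adjusted over the list alone (8.28e-07, and adjusted p = 0.571 with an estimated correlation). Among them were the apelin receptor gene Aplnr (−1.78 ± 0.365, edgeR adjusted p = 0.0149), Tie1 (−0.68 ± 0.151, 0.0189) and Tek, the angiopoietin receptor gene (−0.91 ± 0.208, 0.0229). With a sex term 1 of 22 endothelial genes passed, as lower, in place of 4, and the edgeR adjusted p was 0.0511 for Tie1 and 0.078 for Tek (over all alternatives 0.00133 to 0.0816 and 0.00107 to 0.102). Notch pathway genes fell, 5 of 22 lower and 9 adjusted over the list alone (0.000886, and adjusted p = 0.284 with an estimated correlation). Nrarp, a target and regulator of Notch, changed by −1.79 ± 0.327 (edgeR adjusted p = 0.00893), Notch1 by −1.03 ± 0.229 (0.0201) and Notch2 by −0.47 ± 0.121 (0.0337).

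Genes linked to denervation rose in old sedentary muscle. Of the 21 measured members of the denervation and neuromuscular junction list 6 rose and 1 fell, with 10 higher and 1 lower adjusted over the list alone. The list passed camera with a preset (adjusted p = 3.48e-07) and with an estimated correlation (adjusted p = 0.0319 with an estimated correlation). Chrnb1, the acetylcholine receptor β subunit, rose from 25.9 ± 4.03 to 62.3 ± 6.98 CPM (1.27 ± 0.161, edgeR adjusted p = 0.0019) and Ankrd1, a stress-responsive sarcomere protein, from 7.63 ± 3 to 57 ± 9.15 CPM (2.90 ± 0.432, 0.00657). Proteasome subunits rose, 8 of 37 higher, and 13 higher and 1 lower adjusted over the list alone (9.17e-06, and adjusted p = 0.598 with an estimated correlation). Psmd4 stood at 114 ± 7.85 and 160 ± 12.1 CPM and Psmc3 at 174 ± 4.55 and 219 ± 13.4 CPM. Calcium handling genes rose, 3 of 22 higher and 7 adjusted over the list alone (0.000886, and adjusted p = 0.571 with an estimated correlation). B and plasma cell markers rose, 1 of 9 higher also adjusted over the list alone (0.000138, and adjusted p = 0.571 with an estimated correlation). The antibody heavy chain Ighg2c stood at 0.27 ± 0.256 and 16.6 ± 0.677 CPM (5.91 ± 0.93, edgeR adjusted p = 0.00809). Erythroid genes rose (0.00735, and adjusted p = 0.641 with an estimated correlation), with 0 of 8 past adjusted over the list alone. These 10 lists kept their call without any 1 of the 6 sedentary libraries.

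Circadian clock genes rose as a list by a median of 0.44 (camera adjusted p = 0.0262, and adjusted p = 0.284 with an estimated correlation), with 5 of 18 higher and 2 lower, and 6 higher and 3 lower adjusted over the list alone. The call was lost without young sedentary library 1 (0.0639). The clock repressor Cry2 rose from 29 ± 4.45 to 63.6 ± 9.91 CPM (1.13 ± 0.131, edgeR adjusted p = 0.0013) and Tef from 238 ± 37.7 to 371 ± 27 (0.64 ± 0.114, 0.00815). Npas2 fell from 2.86 ± 1.52 to 0.401 ± 0.268 (−2.83 ± 0.612, edgeR adjusted p = 0.0181). Immediate-early genes fell, 4 of 24 lower and 1 higher, and 5 lower and 1 higher adjusted over the list alone (0.0169, and adjusted p = 0.641 with an estimated correlation). They lost the call without old sedentary library 4 (0.0838) or young sedentary library 3 (0.18). Klf4 fell from 31.4 ± 7.09 to 10.4 ± 0.304 CPM (−1.59 ± 0.134, edgeR adjusted p = 0.0002). Cell cycle genes fell, 4 of 21 lower and 9 adjusted over the list alone (0.000886, and adjusted p = 0.764 with an estimated correlation), a call lost without young sedentary library 2 (0.258), the library with skin keratins. Ccnd1, cyclin D1, changed by −1.26 ± 0.226 (edgeR adjusted p = 0.00815). Adipocyte markers fell, 1 of 19 lower also adjusted over the list alone (0.00147, and adjusted p = 0.764 with an estimated correlation), a call lost without young sedentary library 1 (0.133). Schwann cell and nerve markers fell, 1 of 13 lower also adjusted over the list alone (0.0262, and adjusted p = 0.598 with an estimated correlation), and lost the call without old sedentary library 4 (0.0838) or young sedentary library 3 (0.0825). Ribosomal proteins rose by a median of 0.07 (0.0122, and adjusted p = 0.928 with an estimated correlation), with 2 of 85 higher and 0 adjusted over the list alone, a call lost without young sedentary library 3 (0.104).

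Single genes outside these groups changed as well. Mss51, a muscle gene of mitochondrial regulation, rose from 19.1 ± 3.67 to 163 ± 45.1 CPM (3.09 ± 0.428, edgeR adjusted p = 0.00549) and stood at 48.8 ± 22 CPM in old exercised muscle. Ostn, the secreted peptide musclin, rose from 3.89 ± 1.57 to 28.4 ± 10.5 CPM (2.87 ± 0.525, edgeR adjusted p = 0.013). Trdc, a γδ T cell receptor gene, rose from 0.324 ± 0.0924 to 2.65 ± 0.951 CPM (3.02 ± 0.39, 0.0019) and Tekt1, a ciliary tektin, from 0.974 ± 0.386 to 7.61 ± 2.16 CPM (2.96 ± 0.288, 0.000781). The intermediate filament gene Des rose by 0.67 ± 0.102 (edgeR adjusted p = 0.00444), the laminin receptor gene Itga7 by 0.50 ± 0.068 (0.00264), the autophagy gene Map1lc3a by 0.83 ± 0.165 (0.0124) and the NRF2 target Nqo1 by 0.77 ± 0.17 (0.0192). The noncanonical NF-κB genes Relb (0.96 ± 0.195, 0.0129) and Nfkb2 (1.25 ± 0.282, 0.0235) rose, and Igf1, the growth factor of muscle, fell from 37.2 ± 13 to 14.9 ± 4.46 CPM (−1.32 ± 0.314, 0.0291). The largest negative folds, of Lrrc15 (−6.33 ± 1.682, edgeR adjusted p = 0.0453) and Fgfr2 (−4.96 ± 1.063, 0.0191), came with young sedentary means of 7.76 ± 12.5 and 3.83 ± 4.54 CPM, and Lrrc15 reached 22.1 CPM in a single young sedentary library.

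With a sex term fewer members of several lists passed. Higher were 3 of 21 denervation genes in place of 6, 3 of 37 proteasome subunits in place of 8 and 3 of 18 clock genes in place of 5. Lower were 20 of 36 matrix genes in place of 25, 5 of 15 fibroblast markers in place of 7, 1 of 11 tendon markers in place of 4, 3 of 22 Notch genes in place of 5, 2 of 24 immediate-early genes in place of 4, and 0 clock, 0 adipocyte and 0 Schwann cell genes. More cell cycle genes were lower, 8 of 21 in place of 4. The old sedentary libraries were all male by pattern, and the 1 male young sedentary library was library 2, which held skin keratins. The sex-adjusted comparison therefore leans on that library, without which camera lost the cell cycle list (adjusted p = 0.258). With the sex term camera lost the immediate-early (adjusted p = 0.268) and Schwann cell (0.203) lists.

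The count of 1538 genes fell to 315 without old sedentary library 4, 411 without old sedentary library 5 and 660 without young sedentary library 1, and of 44 genes chosen by the naming rule 22 kept their call without any 1 library. Those that lost it in at least 1 such fit include all endothelial and Notch genes named here (Aplnr, Tie1, Tek, Nrarp, Notch1 and Notch2). The others named here are Igf1, Relb, Nfkb2, Nqo1, Npas2, Ostn, Psmc3, Pi16, Kera, Map1lc3a, Lrrc15 and Fgfr2. With a sex term Kera (edgeR adjusted p = 0.1), Npas2 (0.0557) and Nqo1 (0.0611) missed the threshold too, with ranges over all alternatives of 0.000362 to 0.129, 0.000243 to 0.0875 and 0.000676 to 0.0753. A fit of only the 2 groups called 876 and a sex term 994, of which 761 were shared with the 1538, and DESeq2 called 2308 and limma voom 2668.

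**Figure D3:**
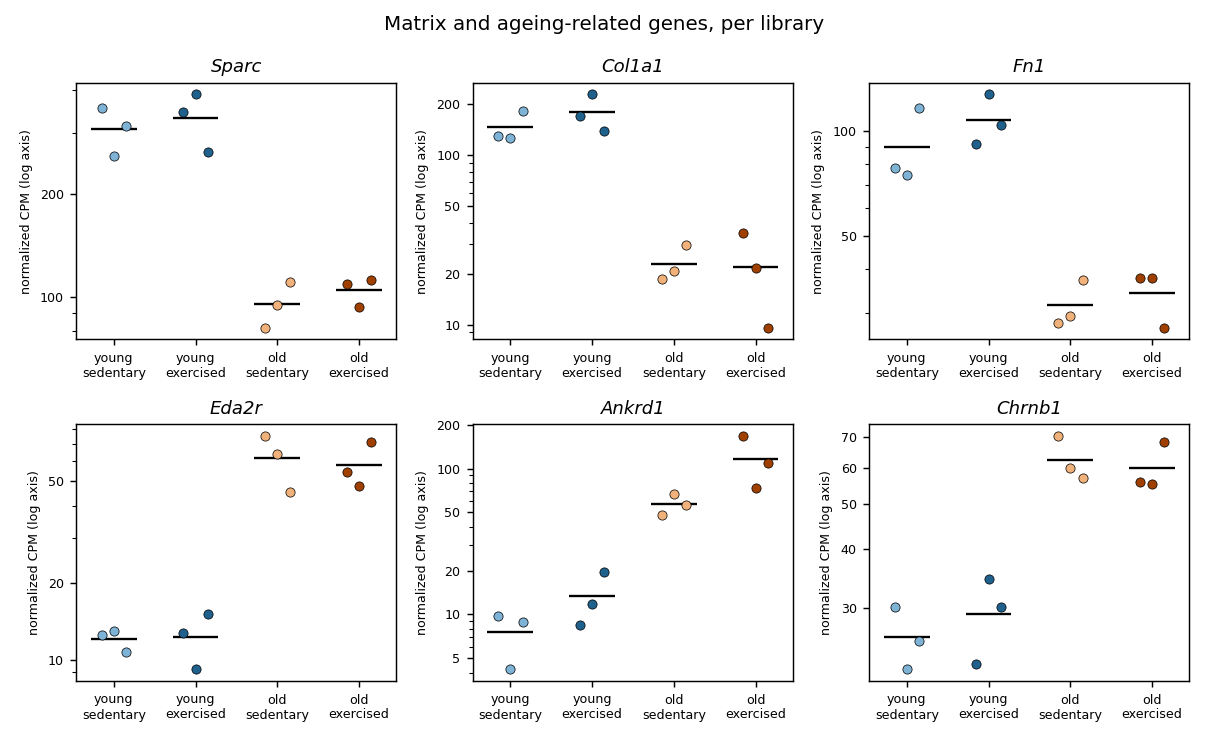
Normalised CPM (log y axes, which differ between panels) of 6 genes in each of the 12 libraries by group (x axes), with points for libraries and bars for the mean of 3. Sparc lay at 257 to 389 CPM in young and 81.6 to 112 CPM in old libraries, Col1a1 at 127 to 229 and 9.58 to 34.8, and Eda2r at 9.22 to 15.1 and 45.4 to 75.2.

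The fifth comparison set old against young exercised muscle. Of 36 extracellular matrix genes 26 were lower in old mice (camera adjusted p = 6.17e-37, and adjusted p = 0.122 with an estimated correlation). Col1a1, the main chain of type I collagen (chromosome 11, 94936224 to 94953042), fell from 180 ± 45.8 to 22 ± 12.6 CPM (n = 3 each), a log2 fold change of −3.03 ± 0.432 (edgeR adjusted p = 0.0043). Col5a1 fell from 51.3 ± 8.98 to 12.6 ± 3.13 CPM (−2.03 ± 0.248, edgeR adjusted p = 0.00172), fibronectin Fn1 from 108 ± 18 to 34.3 ± 6.09 CPM (−1.65 ± 0.204, 0.00166) and Sparc from 333 ± 62.9 to 105 ± 9.64 CPM (−1.67 ± 0.164, 0.000506). Ucp3 was lower in old exercised muscle (271 ± 40.2 against 82.6 ± 22.5 CPM, −1.72 ± 0.26, edgeR adjusted p = 0.0043), as was Ppargc1a (−1.13 ± 0.229, 0.0132). Sln, the peptide sarcolipin that inhibits the calcium pump, rose from 0.258 ± 0.161 to 27 ± 18.4 CPM (6.67 ± 0.945, edgeR adjusted p = 0.0043). In all, 704 genes were higher and 807 lower in old mice, 350 and 272 of them by at least 2-fold.

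Of the 36 matrix genes 0 rose and 10 did not pass over all genes, 27 were lower and 1 higher adjusted over the list alone, and the median was −1.39. Tendon markers fell, 7 of 11 lower and 1 higher, and 10 lower and 1 higher adjusted over the list alone (2.61e-13, and adjusted p = 0.214 with an estimated correlation). Among them were Kera (−4.21 ± 0.56, edgeR adjusted p = 0.00267) and tenomodulin, Tnmd (−2.91 ± 0.455, 0.00465). Fibro-adipogenic and fibroblast markers fell, 8 of 15 and 10 adjusted over the list alone (6.16e-12, and adjusted p = 0.106 with an estimated correlation). Lower members included Clec3b (−1.35 ± 0.113, edgeR adjusted p = 0.000191), decorin, Dcn (−0.83 ± 0.112, 0.00185), and Pi16 (−1.76 ± 0.251, 0.0031). The denervation list rose, 9 of 21 higher and 12 adjusted over the list alone, and passed camera with a preset (1.27e-08) and with an estimated correlation (adjusted p = 0.0375 with an estimated correlation). Chrnb1 (1.04 ± 0.161, edgeR adjusted p = 0.0036), Ankrd1 (3.13 ± 0.43, 0.00367) and the neural adhesion gene Ncam1 (0.99 ± 0.132, 0.0018) were among them. Fast-fibre genes fell, 5 of 17 and 8 adjusted over the list alone (5.16e-05, and adjusted p = 0.461 with an estimated correlation). The lower members included Casq1, the calcium store protein of fast fibres (−0.82 ± 0.13, edgeR adjusted p = 0.00367), Pvalb (−0.86 ± 0.148, 0.00541) and Ampd1 (−0.95 ± 0.141, 0.00281). Slow-fibre genes rose as a list (0.00221, and adjusted p = 0.899 with an estimated correlation) with 0 of 15 past adjusted over the list alone. Myh7 lay at 1.84 to 16.4 CPM in young and 46.9 to 136 CPM in old exercised libraries. Fatty acid oxidation genes rose, 1 of 28 higher and 1 lower, and 9 higher and 1 lower adjusted over the list alone (0.000755, and adjusted p = 0.899 with an estimated correlation), the lower one being Ucp3. Proteasome subunits rose, 4 of 37 and 5 adjusted over the list alone (0.00206, and adjusted p = 0.899 with an estimated correlation). Erythroid genes rose (0.00206, and adjusted p = 0.703 with an estimated correlation) with 0 of 8 past adjusted over the list alone.

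B and plasma cell markers rose, 5 of 9 and 8 adjusted over the list alone (camera adjusted p = 3.18e-05, and adjusted p = 0.582 with an estimated correlation). Higher were Igkc (7.80 ± 1.689, edgeR adjusted p = 0.0246), Ighg2c (4.81 ± 0.824, 0.00902), Jchain (4.83 ± 1.269, 0.044) and Ighm (2.31 ± 0.587, 0.0396). Old exercised library 6 carried much of these differences, with Jchain at 38.4 CPM of the plain total against 1.68 and 2.4 in libraries 4 and 5, and Ighm at 714 against 188 and 221. Without it the log2 fold change was 2.07 for Jchain (edgeR adjusted p = 0.0417), 1.47 for Ighm (0.101) and 4.57 for Igkc (0.00433). With a sex term 1 of the 9 markers passed in place of 5, and the edgeR adjusted p was 0.117, 0.0595 and 0.0678, and over all alternatives the adjusted p ranged from 0.00025 to 0.199, 0.00149 to 0.162 and 0.00433 to 0.268. Igkc lay at 9.1, the lowest, to 295 normalised CPM, the highest, in old exercised libraries and at or below 0.973 in young exercised libraries. These 10 lists kept their call without any 1 of the 6 exercised libraries. The neutrophil genes S100a8 (6.16 ± 1.292, edgeR adjusted p = 0.0148) and Csf3r (2.73 ± 0.485, 0.006) rose, where S100a8 had 2 counts in the 3 young exercised libraries together, so its fitted fold depends on the prior count.

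The other 5 lists that passed camera lost the call without 1 library or another. Nuclear oxidative phosphorylation genes (up, 0.013) had 0.0618 without old exercised library 6 and 0.0571 and 0.0876 without young exercised library 8 or 10. TCA cycle genes (up, 0.0263) had 0.099 without old exercised library 5 and 0.0571 and 0.0972 without young exercised library 8 or 10. NRF2 targets (up, 0.0234) had 0.173 without old exercised library 6, 0.0693 without young exercised library 8 and 0.0735 with a sex term. Calcium handling genes (down, 0.0253) had 0.173 without old exercised library 6 and 0.104 without young exercised library 7, and Camk2b of that list was higher (0.68 ± 0.072, edgeR adjusted p = 0.000676). Ribosomal proteins (up, 0.022) had 0.322 and 0.511 without old exercised library 4 or 6 and 0.174 without young exercised library 7. With an estimated correlation the adjusted p of these lists ranged from 0.582 to 0.976. Adjusted over the list alone, 0 nuclear oxidative phosphorylation, 0 TCA cycle, 6 NRF2 target, 2 higher and 7 lower calcium handling and 0 ribosomal protein genes passed.

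Other genes changed in the same comparison. The glycogen enzymes Gbe1 (1.56 ± 0.176, edgeR adjusted p = 0.00101) and Gys1 (0.57 ± 0.076, 0.00185) rose. So did Itga7 (0.82 ± 0.068, edgeR adjusted p = 0.000191), Des (0.52 ± 0.102, 0.00989), Eda2r (2.22 ± 0.226, 0.000895), the stress hormone Gdf15 (2.96 ± 0.576, 0.00949) and the Notch ligand Dll1 (1.11 ± 0.205, 0.00781). The Wnt inhibitor Wif1 (−4.91 ± 0.717, edgeR adjusted p = 0.00354), the prolyl hydroxylase genes P4ha1 (−0.73 ± 0.161, 0.0166) and P4ha2 (−0.40 ± 0.092, 0.0196) and Nrep (−3.05 ± 0.481, 0.0064) fell.

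The count of 1511 genes fell to 615 without young exercised library 8, 741 without 10 and 954 without 7, and to 991 and 856 without old exercised library 5 or 6. Of 36 genes chosen by the naming rule 30 kept their call without any 1 library. Of the other 6, Igkc, Jchain, Ighm, S100a8, P4ha1 and P4ha2 missed the threshold in at least 1 such fit. Across genes, the age differences in sedentary and exercised mice had a Pearson r of 0.313 and a Spearman rho of 0.319, where genes are not independent replicates, and 61.9% had the same sign. The comparisons share no library, but they come from the same fit with the same estimate of the spread of each gene. In both, more young than old libraries had the female pattern. The expected counts that follow do not allow for this. Both called 204 genes higher (31.4 expected from independent lists) and 256 lower (45.1 expected), and 9 were called in opposite directions.

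**Figure D4:**
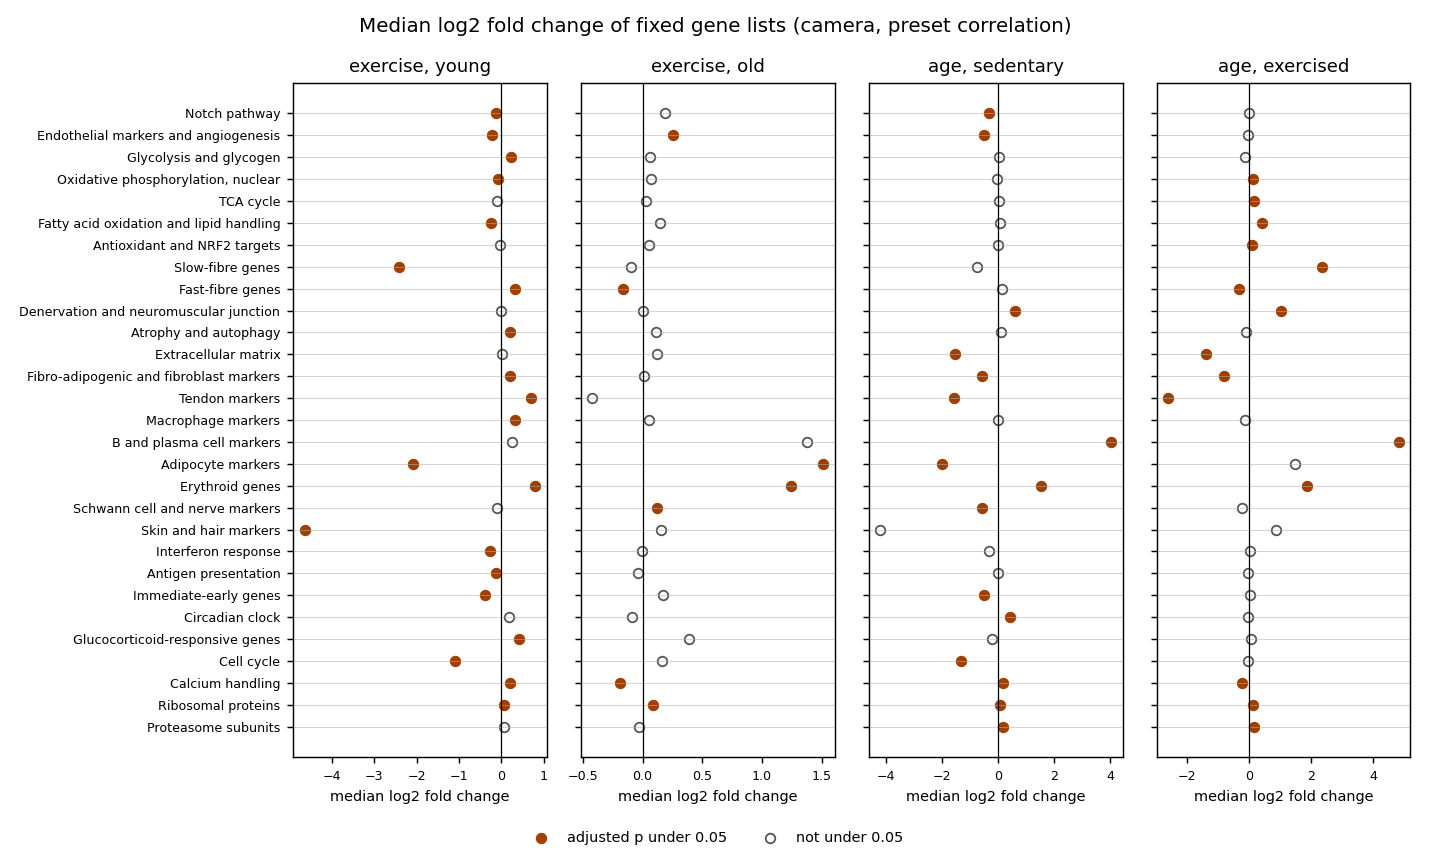
Median log2 fold change (x axes, which differ between panels) of the fixed gene lists (y axis) that passed camera with a preset correlation in at least 1 of 4 comparisons, with filled points for an adjusted p under 0.05 and open points otherwise. The median of the extracellular matrix list was −1.53 and −1.39 in the age comparisons of sedentary and exercised mice, and that of slow-fibre genes −2.42 with exercise in young mice.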

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

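Of the tests in this part only the peripheral myelin test was chosen after its result was seen. The variants of the glial test with 0, 0.01 and 0.5 CPM added were also tried only after its result with 0.1 CPM was seen. What brought the following results here is a difference between groups: the exercise responses of old and young mice passed a test of their difference, by edgeR in the main fit or by camera with a preset correlation. For 8 genes the log2 difference, old minus young, by edgeR was −0.914 for Aff1, −1.786 for Spock2, 2.219 for Kif5a, 6.595 for Jph3, 2.368 for Adcy1, 2.505 for Enc1, 2.845 for Ddn and 2.663 for Tubb4a, the last 6 more positive in old mice. Of these 8 genes 0 kept the call in all 12 fits that left 1 library out. With a sex term, with a replicate block or among genes of at least 5 CPM edgeR called 0, while DESeq2 and limma voom each called all 8. For 13 lists the camera adjusted p with a preset correlation was 0.00328 for Notch pathway, 4.27e-05 for endothelial, 0.00753 for nuclear oxidative phosphorylation, 0.00939 for fatty acid oxidation, 0.000719 for slow-fibre, 1.15e-07 for fast-fibre, 0.00759 for atrophy, 0.000719 for tendon, 1.91e-07 for adipocyte, 0.0247 for skin, 0.021 for immediate-early, 0.00546 for cell cycle and 4.29e-08 for calcium handling genes. With an estimated correlation 0 of these 13 passed (adjusted p from 0.47 to 0.807).

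Grouping by chance was tested by counting calls over splits of the libraries, a test set before. For the difference between responses, 100 of the 200 possible splits were run, the real one and others drawn at random, and 1 of these 100, the real one, had at least 8 called genes, and the highest other had 4. A signal shared by the libraries of 1 group, whatever its source, would give such a result too. The test therefore does not show that the source is an exercise response that differs with age. The 10 splits of 3 against 3 libraries can never give a share under 0.05. In each of the other comparisons 1 of 10 splits reached the real count (2 for exercise in young, 89 for exercise in old, 1538 for age in sedentary and 1511 for age in exercised mice), and the highest other was 0.

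Transcripts known from brain were higher in all 3 old exercised libraries, and RNA from central nervous tissue, from handling or a mixed sample, is a candidate explanation. It could also account for several of the 6 genes above with a more positive response in old mice, such as Kif5a and Tubb4a. In a test set before, with bounds of 0.5 and 1, the median log2 ratio of old exercised over old sedentary mean CPM over 20 astrocyte and oligodendrocyte genes not looked at before was 0.827 with 0.1 CPM added to each mean, an amount the test had not fixed. It was 1.882 with nothing added, 1.491 with 0.01 and 0.445 with 0.5 CPM added, so the result lies above, between or below the bounds by that choice. The direction did not depend on it, since 20 of the 20 genes were higher with each amount, as RNA from central nervous tissue would give. Direction alone does not exclude a response of the muscle, so the 2 explanations cannot be told apart here. Several of these genes are also expressed in this muscle, with Slc4a4 at 18.3, Agt at 7.66 and Tspan2 at 5.87 CPM in old sedentary libraries. Others of the 20 lay near the floor, such as Slc6a11 (0.0368 and 0.621 CPM) and Mog (0.0138 and 0.184) in old sedentary and old exercised libraries. Gfap, an astrocyte filament chosen after its values were seen, stood at 0.368 and 2.56 TMM-normalised CPM in these groups. In mean log2 level with 0.1 CPM added, each old exercised library lay above all other libraries for 3 lists. The lowest old exercised and highest other values were 0.256 and −0.331 for central neurons, 0.494 and 0.156 for astrocytes and −0.979 and −1.238 for oligodendrocytes. This separation does not tell the explanations apart. More peripheral nerve in the sample could raise neuronal RNA too, but the median over 8 peripheral myelin genes was −0.004 with 0.1 CPM added and −0.014 with nothing added, below a bound of 0.5 that was written down only after the values were seen.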

How the results depend on the processing

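Chosen only after results were seen were the sex term, the omission of young sedentary library 2 with old exercised library 6, and the restriction to genes of at least 5 CPM; other alternatives were set before. Of the genes followed through the alternatives none besides Arnt changed direction. Arnt, which never passed, did in those given below. DESeq2 size factors and exclusion of mitochondrially encoded genes left every count within 1.5 times. For the changes below the cause was not tested, except that fewer libraries or genes enter the fits that leave some out. Counts are given as young exercise, old exercise, difference of responses, age in sedentary and age in exercised mice, against 2, 89, 8, 1538 and 1511.

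Without a filter on low counts the young exercise count was 18 and the difference count 27, and 11 lists passed for old exercise (7 before) and 20 for the difference (13 before). DESeq2 called 242, 185, 430 and 2308 genes in the first 4 comparisons, and limma voom 59, 140, 71 and 2668, with an Arnt difference of 0.012. Fits of only the 2 groups called 57 genes for old exercise and 876 for age in sedentary mice. A sex term gave 10 for young exercise, 0 for the difference (edgeR, 2434 at an unadjusted p under 0.05), 994 for age in sedentary mice, and 11 lists for old exercise. Without young sedentary library 2 and old exercised library 6 the counts were 62, 39 and 61 in the first 3 comparisons, the Arnt difference 0.076 and the correlation of exercise responses −0.113. Among genes of at least 5 CPM edgeR called 0 for old exercise (666 at an unadjusted p under 0.05) and 0 for the difference (1339), with an Arnt difference of 0.025 and 15 lists for old exercise. Camera with an estimated correlation passed 0, 0, 0, 1 and 1 lists, and fry 0, 0, 0, 9 and 5. The correlation of exercise responses was −0.06 among genes past 0.05 in either comparison, and that of age differences 0.537 among such genes and 0.447 among genes of at least 10 CPM.

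With 1 library left out, counts ranged from 0 to 33 for young exercise, 10 to 63 for old exercise, 0 to 57 for the difference, 315 to 1630 for age in sedentary and 615 to 1273 for age in exercised mice. Lists passed ranged from 16 to 21, 6 to 12, 11 to 15, 15 to 18 and 13 to 19. Arnt ranged from −0.01 to 0.16, 0.008 to 0.125, −0.09 to 0.079, 0.118 to 0.221 and 0.073 to 0.243, and passed in none. Correlations ranged from −0.273 to −0.089 (exercise) and 0.248 to 0.35 (age).

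Old sedentary and old exercised libraries share the numbers 4, 5 and 6. A replicate block in the old libraries gave 29 genes for old exercise and 0 for the difference (edgeR, 2182 at an unadjusted p under 0.05). Same-numbered libraries correlated at −0.104, 0.039 and 0.077 in their deviations from the group means and others at −0.19 to 0.18, so the data give no pairing. Depth limits genes below about 1 CPM, which have fewer than 28 counts per library.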

Other observations

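The tests in this part, of the sex term and of matrix genes, were chosen only after the results were seen. Odf3l2 (chromosome 10, 79639526 to 79645738), chosen after its values were seen, stood at 3.83 ± 3.28 CPM in young sedentary, 46 ± 6.66 in young exercised, 20.2 ± 8.23 in old sedentary and 6.58 ± 2.8 in old exercised muscle, with an edgeR adjusted p of 0.119 for exercise in young, 0.41 in old mice and 0.0672 for the difference. Further brain transcripts chosen after their values were seen were Slc17a7, a vesicular glutamate transporter (log2 fold change 3.05 with exercise in old mice, edgeR adjusted p = 0.00816), and Mobp, a myelin gene of the brain (3.02, 0.00816).

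Unequal numbers of male and female libraries might explain age differences, since 4 of 6 young and 1 of 6 old libraries had the female pattern. With a sex term the slope of adjusted on unadjusted log2 fold changes of the 1538 genes called in sedentary mice was 0.962 (95% interval 0.953 to 0.97), above the bound of 0.5, and 1538 kept their sign, while 761 were still called. The interval takes genes as independent replicates, which they are not, so it does not measure the uncertainty of the sex effect. Of the 1538 genes, 1533 had no overlap between old and young sedentary libraries. For these the male young library differed from the old ones, all male by pattern, in the same direction as the female ones. Genes that follow sex alone would place that library with the old ones and would rarely be called. The slope over called genes could therefore hardly fall below the bound, and it does not show how much sex adds to the age differences.

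Lower matrix genes in old muscle could follow from fewer fibroblasts. The matrix list differed by −1.383 in mean log2 level between old and young libraries and 10 fibroblast markers that are not matrix genes by −0.723, and the difference of both was −0.661 with an exact two-sided permutation p of 0.00216 over 924 splits, the smallest these can give. The 10 markers, given here as CPM of the library's plain total, did not move alike. From young to old sedentary muscle Pi16 stood at 42.4 and 15.3 CPM, Dpp4 at 8.76 and 2.89, Cd248 at 15.7 and 5.82 and Pdgfrl at 1.78 and 0.464, falls about as large as that of the matrix list or larger. The other markers fell by less or rose. Pdgfra stood at 30.1 and 18 CPM, Hic1 at 10.6 and 6.79, Ly6a at 41.4 and 29.5 and Cxcl14 at 58.2 and 46.8. Osr1 stood at 3.4 and 3.32 CPM and Apod, which rose, at 29.7 and 46.6. Because the mean of these markers depends on which are chosen, the test does not exclude fewer fibroblasts, or fewer of 1 kind, and that explanation stays open. Within male libraries (5 old, 2 young) the matrix list differed by −1.196, with the highest old level at 4.108 and the lowest young at 4.827, which argues against sex as its only source. The 2 young male libraries were young sedentary library 2, which held skin keratins (4.827), and young exercised library 7 (5.146). Both lay below every young female library (lowest 5.152), and the old female library was the highest old one (4.292). Sex may therefore add to the difference.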
